A study of Homo sapiens with 4 samples.

How the data were processed

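RNA from U87 cells carrying the empty vector (shNC, 2 libraries) or the hairpin against PTPRN (shPTPRN3, 2 libraries) was sequenced after preparation with a stranded mRNA kit, per the labels' protocols. Per the submitters' processing notes, the authors used FastQC 0.72, STAR 2.6.0b-1 and Cufflinks 2.2.1.2 with genome build hg38; the annotation, the strand setting and other options are not given in the sources used here. The deposited values are FPKM, fragments normalised to transcript length and to the number of mapped fragments, in a Cufflinks gene table per library with a confidence interval and a status for each of 33646 gene rows, per the file headers. FPKM depend on the transcript length assumed for each gene and on how fragments are shared among overlapping genes and paralogues, and with the strand setting not given, overlapping genes on opposite strands cannot be told apart with certainty.

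The tables hold no fragment counts. Depth was estimated from interval widths of single-exon genes, taking the interval as a counting error, at 21.5, 14.2, 31.8 and 14.8 M fragments for shNC replicates 1 and 2 and shPTPRN3 replicates 1 and 2. Steps between low FPKM gave relative depths of 0.629, 1.65 and 0.644 for the last 3 libraries against the first. Only 33.6% to 52.1% of the low values compared fell on such a step within a log2 tolerance of 0.004, so whole counts could not be recovered and no count model was used. The intervals cover counting and assignment error within a library, not the spread between cultures.

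Rows were joined on gene name and position. Rows with a status other than OK in any library were left out (651 rows), and the rest were summed per symbol, which gave 27940 symbols. FPKM were scaled by a median-ratio factor per library (1.04, 0.974, 1.05 and 0.943) over the 9988 genes at 1 FPKM or more in every library. Genes with a mean of at least 1 FPKM were tested, with PTPRN always kept. The test was limma 3.58.1 in R 4.3.3 on log2(scaled FPKM + 1), moderated with a trend (eBayes), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on that log2 scale, where the pseudocount of 1 understates the changes of low genes. The residual degrees of freedom were 2 and the prior added 4.94. A gene listed at 0 is given by its library values, with no fold.

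Gene lists (44 lists, 1149 symbols) were written before the data were examined and tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 41 lists with at least 5 tested members. The same lists were tested with an estimated correlation, with fry and with a rank test. Counts of members are given over all genes tested and adjusted over the list alone. Named genes followed a rule fixed at the same time: PTPRN and PTPRN2, up to 12 called genes per direction with the largest fold change among those whose groups did not overlap and whose higher group had a mean of at least 5 FPKM, up to 4 called members of each list past the threshold or the 2 largest where none was called, and GAPDH and ACTB. Small RNAs, ribosomal protein pseudogenes, uncharacterised loci and Y-linked genes were left out of the top genes. Other members of lists, the partners of overlapping genes, HNRNPUL1 and the further called genes never listed at 0 were named after their values were seen. Named genes of the repeated fit follow the same rule applied to that fit.

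On simulated values for 11394 genes, with spreads drawn from the fitted prior, the comparison of shPTPRN3 with shNC recovered 1 of 67 genes changed by 1 on the log2 scale, 20 of 67 changed by 2 and 56 of 66 changed by 3, with 3 false calls. A G2/M list shifted by -1 in a second simulation with independent genes passed camera (adjusted p = 1.35e-28), and 0 of the 40 other lists did. With an estimated correlation the shifted list had adjusted p = 0.280. In the data, the correlation estimated among members was 0.504 for G2/M, 0.0128 for proteases and 0.988 for ribosomal proteins. The simulation therefore does not show how often camera at its preset correlation passes lists falsely where members move together.

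Positions are those of the tables (hg38), given from 1. GENCODE 29 on the same build supplied transcripts, lengths and 3' UTRs; of 25500 symbols shared with it, 98.9% overlapped the gene of the same name. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 joined the tables, and matplotlib 3.10.9 drew the figures. The fit without genes listed at 0 was also repeated without each library and under other scalings. Alternatives covered scaling, pseudocount, filters, row handling, eBayes settings, thresholds, the replicate number as a block, leaving out each library, and, added after seeing the data, leaving out genes listed at 0, leaving out alternate sequences and removing trends with transcript length and GC content. Other samples and loci were not analysed here.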

Results

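The series holds 4 RNA-seq libraries of U87 cells, an established human glioma cell line, in 2 groups of 2. The control group, called shNC, received a lentivirus made from the empty vector, per the labels' protocol. The series' design text names the control H1-RFP (WT) instead, so the exact control vector is uncertain. The knockdown group, called shPTPRN3, received a lentivirus carrying a short hairpin RNA against PTPRN, a receptor-type protein tyrosine phosphatase family member of the membrane of dense-core secretory vesicles. The comparison asks what changes in the transcriptome of these cells when the hairpin is present, in a study whose title concerns cell growth. The series' design text calls the libraries biological replicates and does not say whether they came from separate cultures, so the p-values measure the spread between these libraries, which may be partly technical. Depth, estimated from the widths of the deposited confidence intervals, was 21.5 M fragments in shNC replicate 1, 14.2 M in shNC replicate 2, 31.8 M in shPTPRN3 replicate 1 and 14.8 M in shPTPRN3 replicate 2. Across 11394 tested genes, the log2 values of the replicates correlated with r = 0.922 in shNC and r = 0.936 in shPTPRN3, against 0.847 to 0.924 for pairs from different groups. These correlations are across genes, which are not independent replicates.

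PTPRN itself stood at 28.6 and 19.3 FPKM in the shNC libraries and at 5.22 and 3.42 FPKM in the shPTPRN3 libraries, as deposited. The group means were 24.0 ± 6.58 and 4.32 ± 1.28 FPKM (SD, n = 2). After scaling, 18.1% of the control level was left, with 18.0% within the libraries numbered 1 and 18.3% within those numbered 2. The gene lies on chromosome 2, from 219289623 to 219309401 on the minus strand (hg38). The hairpin's target sequence, GGAAGTCTGTATTCAGGATGG, matched PTPRN and no other annotated gene, in 11 of its 19 annotated transcripts. In transcript ENST00000295718.6 the match lies in the coding sequence and spans the junction of exon 2 (219307792 to 219307808) and exon 3 (219307554 to 219307557). The deposited confidence intervals of the control libraries (27.2 to 30.1 and 17.9 to 20.7 FPKM) did not overlap those of the knockdown libraries (4.79 to 5.66 and 2.90 to 3.94 FPKM). The log2 fold change was -2.22 with an SE of 0.34, and limma's adjusted p of 0.0594 over all genes missed the threshold of 0.05. It passed at 0.0397 without shPTPRN3 replicate 1, and over 18 unblocked alternatives the adjusted p ran from 0.0216 to 0.211. An exact permutation test of 2 against 2 values gave p = 0.333, two-sided, the smallest this design allows. The paralogue PTPRN2 had a log2 fold change of -0.56 (limma, adjusted p = 0.587).

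**Figure D1:**
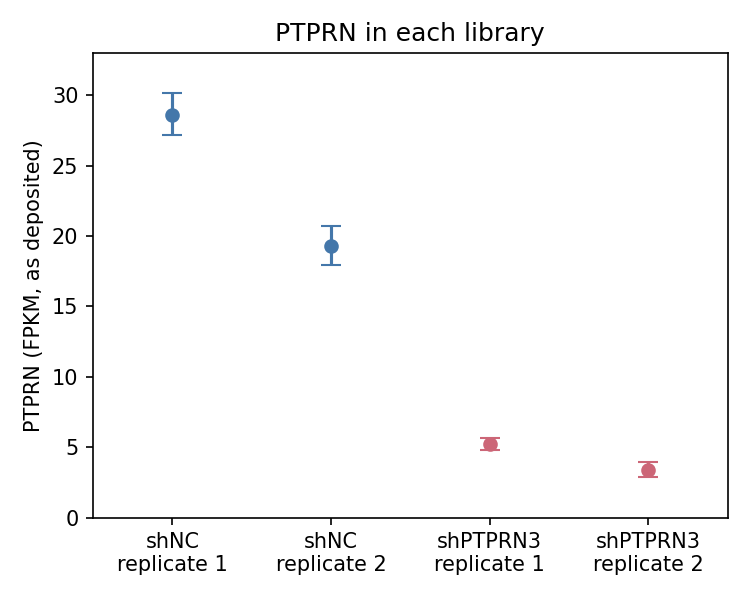
PTPRN in each library, in FPKM as deposited (y axis), for 2 shNC and 2 shPTPRN3 libraries (x axis). Points are the deposited values and bars the authors' confidence intervals. The shNC libraries sit at 28.6 and 19.3 FPKM and the shPTPRN3 libraries at 5.22 and 3.42 FPKM.

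Genes of cell division were lower in the shPTPRN3 libraries. The list of G2/M and mitosis genes, which holds the kinases, cyclins and motor proteins of chromosome segregation, fell with a median log2 fold change of -2.42, or 5.36-fold lower, over 41 tested members. The list of G1/S and replication genes, with the replicative helicase and its loading factors, fell with a median of -1.48 over 41 members. CDK1, the kinase that drives entry into mitosis, fell from 25.2 ± 7.27 to 1.31 ± 1.27 scaled FPKM (SD, n = 2), and MKI67, the proliferation antigen, from 25.0 ± 13.2 to 1.23 ± 0.945. PLK1, CDC20 and the nucleotide synthesis genes TK1 and RRM2 had log2 fold changes of -3.39, -3.31, -3.31 and -3.10.

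Both cell-cycle lists passed camera with its preset correlation (adjusted p = 9.95e-37 for G2/M and 4.29e-28 for G1/S). For each of them the call was lost at adjusted p = 0.582 with an estimated correlation. That test also missed the simulated G2/M list of independent genes, which was shifted by -1 beside 40 unshifted lists (camera, adjusted p = 0.280). Adjusted over the list alone, 39 of the 41 G2/M genes and 34 of the 41 G1/S genes fell and none rose. Adjusted over all genes tested, 5 and 2 of them fell. The G2/M members called over all genes included CDK1, MKI67, KIF20A and CDCA8. The G1/S members were UHRF1 and RFC4, and RFC4 was listed at 0 in both shPTPRN3 libraries. Without shNC replicate 1, CDK1 (-3.30, adjusted p = 0.126) and UHRF1 (-2.78, adjusted p = 0.131) missed the threshold and MKI67 (-4.04, adjusted p = 0.0417) passed it. Without shNC replicate 2, CDK1 (-3.89, adjusted p = 0.158), MKI67 (-2.97, adjusted p = 0.202) and UHRF1 (-3.02, adjusted p = 0.193) missed it. The calls over all genes depended on the settings. By limma, 0 G2/M members were called on FPKM as deposited, on TPM, with a pseudocount of 0.1, with no filter on low values, at a mean of at least 5 FPKM, with eBayes without a trend and without shNC replicate 2. In those fits 32 to 39 members fell over the list alone, the same numbers that had an unadjusted p under 0.05. With quantile normalization, a pseudocount of 0.5 or without shNC replicate 1, 2 were called, against 28 with robust eBayes, 29 without shPTPRN3 replicate 1 and 32 with length and GC trends removed. For G1/S the number was 0 with no filter (35 at an unadjusted p under 0.05), 12 with robust eBayes, 14 without shPTPRN3 replicate 1 and 17 with trends removed. It was 1 on FPKM as deposited, on TPM, with a pseudocount of 0.1, at a mean of at least 5 FPKM, with eBayes without a trend and without either shNC library. Both shPTPRN3 values lay below both shNC values for 40 of 41 G2/M and 41 of 41 G1/S members, an order that chance gives to 16.7% of genes. Over all tested genes, the groups did not overlap in either direction for 44.6%, against 33.3% by chance. Members of a list are not independent draws. Within the libraries numbered 1 the G2/M median was -2.00, and within those numbered 2 it was -3.01. The G1/S medians were -1.32 and -1.66.

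A list of DNA repair genes, many of them of homologous recombination, fell with a median log2 fold change of -0.85 over 30 members (camera, adjusted p = 3.36e-10). This list too had adjusted p = 0.582 with an estimated correlation. Over the list alone 14 members fell, among them FANCI (-2.06), RAD51AP1 (-2.03), BRCA1 (-1.82) and CLSPN (-1.80), while over all genes tested only RAD54L passed, which was listed at 0 in both shPTPRN3 libraries. The kinase gene ATM (0.18) had a value near 0. The DNA repair median was -0.46 without shNC replicate 2, 7 members fell over the list alone without shPTPRN3 replicate 2, and the list missed the threshold (adjusted p = 0.0509) when the genes tested needed a mean of at least 5 FPKM, which left 12 members with a median of -0.40, of which 1 fell over the list alone.

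**Figure D2:**
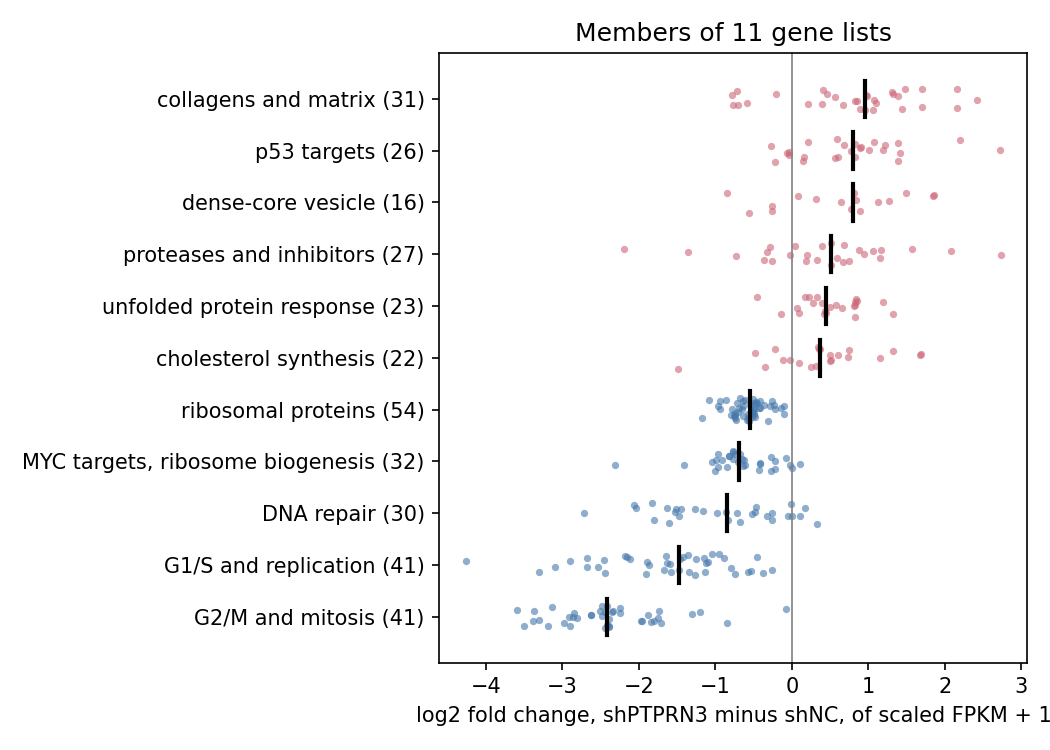
Log2 fold changes (x axis, shPTPRN3 minus shNC, of scaled FPKM + 1) of the members of the 11 gene lists that passed camera with its preset correlation (y axis, number of tested members in parentheses). Each point is a gene, blue for lists that were lower and red for lists that were higher, and black bars are medians, from -2.42 for G2/M and mitosis to 0.96 for collagens and matrix.

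Targets of the tumour suppressor p53 were higher in the shPTPRN3 libraries, with a median log2 fold change of 0.80 over 26 members (camera, adjusted p = 4.23e-07; adjusted p = 0.582 with an estimated correlation). CDKN1A, the inhibitor of cyclin-dependent kinases, had 116 ± 37.6 scaled FPKM in shNC and 763 ± 219 in shPTPRN3 (SD, n = 2). BTG2, an antiproliferative factor, had 3.46 ± 0.637 and 19.7 ± 4.49. Over the list alone 5 members rose (CDKN1A, BTG2, FAS, SESN1 and RRM2B) and none fell, and over all genes tested none passed. MDM2 (0.57) and BAX (-0.03) passed neither. Over the list alone 0 members rose without shNC replicate 2, 2 without shPTPRN3 replicate 1 and 1 without shPTPRN3 replicate 2, while the list itself passed camera each time. With no filter on low values 3 members rose over the list alone, and with length and GC trends removed 12 did. The median was 0.53 within the libraries numbered 1 and 1.00 within those numbered 2.

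Genes of collagens and other extracellular matrix proteins were higher as well, with a median log2 fold change of 0.96 over 31 members (camera, adjusted p = 3.42e-07; adjusted p = 0.727 with an estimated correlation). With no filter on low values the median was 0.53 over 44 members (adjusted p = 2.79e-06). Over the list alone 9 members rose and none fell, and over all genes tested none passed. SPARC, a collagen-binding matrix glycoprotein, had 36.1 ± 2.35 scaled FPKM in shNC and 199 ± 41.3 in shPTPRN3. COL1A2, a chain of type I collagen, had 77.0 ± 13.5 and 346 ± 32.6, and FBN1, fibrillin, 8.94 ± 3.78 and 41.8 ± 0.713. The matrix list's median was 1.2 within the libraries numbered 1 and 0.46 within those numbered 2. Within the libraries numbered 1 the difference between shPTPRN3 and shNC also correlated with transcript length across genes (rho = 0.322, against -0.0161 within those numbered 2), from a median of -0.39 for transcripts under 1000 bases to 0.20 for those of at least 4000 bases. With length and GC trends removed the list's median was 0.83 (camera, adjusted p = 2.73e-06), and 13 members rose and 1 fell over the list alone. The list passed camera without any 1 of the libraries, but over the list alone 0 members rose without shNC replicate 1, and 3 without shNC replicate 2 or without shPTPRN3 replicate 1. On TPM or at a mean of at least 5 FPKM 5 members rose over the list alone, and with no filter 4.

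Smaller shifts upward were found in genes of dense-core vesicles and neuroendocrine secretion (median 0.79 over 16 members, adjusted p = 0.00184), the unfolded protein response (0.45 over 23, adjusted p = 0.00101), cholesterol synthesis (0.36 over 22, adjusted p = 0.00966) and extracellular proteases with their inhibitors (0.52 over 27, adjusted p = 0.00966), all by camera. The vesicle and protease lists had adjusted p = 0.582 with an estimated correlation, and the other lists adjusted p = 0.604 with an estimated correlation. With no filter on low values the vesicle median was 0.11 over 27 members (adjusted p = 0.0118). Of the vesicle genes, of which PTPRN2 is a member and PTPRN was not, CADPS, CPE and SCG2 rose over the list alone, with CADPS at 1.86 and CPE, a prohormone-processing carboxypeptidase, at 1.85. INSIG1 (1.68) and HMGCS1 (1.67) were among 4 cholesterol genes that rose over the list alone, while EBP (-1.48) fell. Among the proteases, MMP3 (2.73), MMP10 (2.08), ADAM19 (1.58) and MMP15 (1.17) rose over the list alone and the urokinase gene PLAU (-2.19) fell. No unfolded protein response gene passed over the list alone, with DNAJB9 at 1.33 and HYOU1 at 1.19. None of these 4 lists had a member called over all genes tested. Without shPTPRN3 replicate 1 all 4 missed the threshold, with adjusted p from 0.0510 to 0.0732 and medians of 0.47, 0.44, 0.41 and 0.26, and without shNC replicate 1 the cholesterol list (median 0.22, adjusted p = 0.0763) and the protease list (adjusted p = 0.0724) did so. The cholesterol median was 0.60 without shNC replicate 2. Over the list alone the cholesterol genes that rose numbered 0 without shNC replicate 1, shNC replicate 2 or shPTPRN3 replicate 2 and 1 without shPTPRN3 replicate 1, and the protease genes 0 without shNC replicate 2 and 2 without either library numbered 1. With no filter on low values limma called 0 protease genes in either direction over the list alone (7 higher and 1 lower at an unadjusted p under 0.05). At a mean of at least 5 FPKM 1 protease gene rose, 1 fell and the list missed the threshold of camera (adjusted p = 0.0792), and 1 vesicle gene rose. On FPKM as deposited or TPM 2 cholesterol genes rose over the list alone.

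Genes of ribosome biogenesis and other MYC targets fell by a median of 0.69 on the log2 scale over 32 members (camera, adjusted p = 1.18e-06; adjusted p = 0.582 with an estimated correlation). Their only member past the threshold, over the list alone or over all genes, was POLR1B, listed at 0 in both shPTPRN3 libraries. The median was -0.45 without shNC replicate 1. The 54 ribosomal protein genes had a median of -0.54 and passed camera (adjusted p = 5.43e-04), but with adjusted p = 0.925 with an estimated correlation and with no member past the threshold over the list alone. RPS2 had -1.18 and RPL12 -1.08. Single libraries decided the ribosomal protein result: the median was -0.05 without shNC replicate 1 (adjusted p = 0.885) and -0.20 without shPTPRN3 replicate 2 (adjusted p = 0.511), against -1.12 without shNC replicate 2 and -0.93 without shPTPRN3 replicate 1. The share of all FPKM in transcripts shorter than 1000 bases, the class of most ribosomal protein mRNAs, was 27.9% in shNC replicate 1, 19.2% in shNC replicate 2, 23.0% in shPTPRN3 replicate 1 and 16.2% in shPTPRN3 replicate 2.

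Gene by gene, limma called 48 of 11394 genes at an adjusted p under 0.05, 9 higher and 39 lower in shPTPRN3, all of them by more than 2-fold. With the FPKM rescaled to TPM the split was 10 higher and 20 lower. The 10 genes that were never listed at 0 were all lower. Of these, 5 belong to the cell-cycle lists, CDK1, MKI67, CDCA8 and TPX2 to G2/M and UHRF1 to G1/S. SHCBP1, NCAPG, CDCA5, PRR11 and HNRNPUL1 belong to none of the fixed lists. HNRNPUL1, an RNA-binding protein gene, stood at 65.7 and 81.3 scaled FPKM in shNC and 14.1 and 12.8 in shPTPRN3. The remaining 38 were listed at an FPKM of exactly 0 in at least 1 library, and 37 of them in both libraries of a group (28 in shPTPRN3, 9 in shNC). The largest lower value was that of PLTP, a phospholipid transfer protein, with 159 and 111 scaled FPKM in shNC, followed by RUVBL1 with 44.2 and 32.6, SNAPIN with 34.4 and 20.2, and RFC4 with 20.4 and 16.2, all listed at 0 in both shPTPRN3 libraries. PEX10, WDR83, PIMREG, CD3EAP and PDSS1 were also listed at 0 there, and KIF20A in 1 of the 2. Of the genes called higher, ANAPC11 (87.5 and 45.0), SLX1A (44.1 and 44.2), SLC31A2 (15.4 and 22.0), CNOT2-DT (12.4 and 7.97), MTIF3 (9.88 and 9.87), MAP3K12 (9.46 and 9.76) and MMP19 (8.32 and 5.25) had these scaled FPKM in shPTPRN3 and were listed at 0 in both shNC libraries. Each of the 37 genes lies in a locus that overlaps another gene of the tables, as did 28.5% of the other tested genes, and an FPKM of exactly 0 at such a locus can be a failed estimate. The number called was 199 without shPTPRN3 replicate 1 (36 higher, 163 lower) and 74 without shPTPRN3 replicate 2 (26 higher), with 18 higher without shNC replicate 1 and 59 lower without shNC replicate 2. Of the 10 genes never listed at 0, 1 was called without shNC replicate 1, 0 without shNC replicate 2, 9 without shPTPRN3 replicate 1 and 4 without shPTPRN3 replicate 2.

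**Figure D3:**
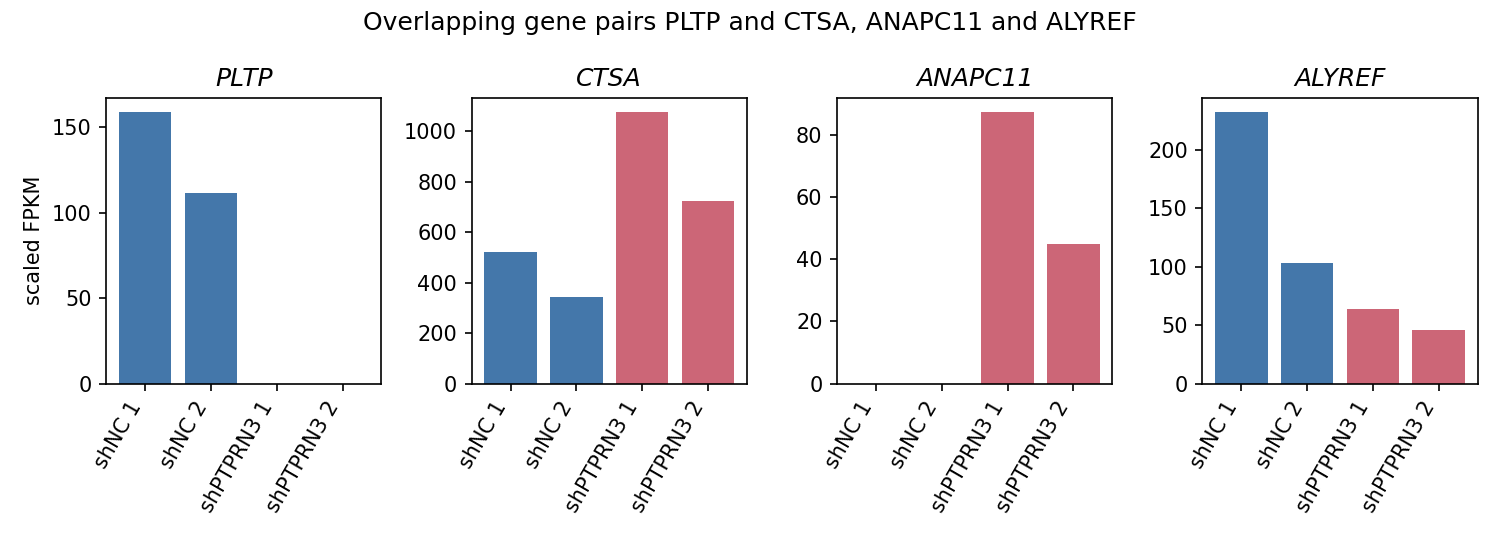
Scaled FPKM (y axis, bars from 0) in each of the 4 libraries (x axis; blue shNC, red shPTPRN3) for the overlapping gene pairs PLTP and CTSA, and ANAPC11 and ALYREF. PLTP is listed at 0 in both shPTPRN3 libraries, where CTSA is at 1078 and 722 against 523 and 343 in shNC, and ANAPC11 is listed at 0 in both shNC libraries, where ALYREF is at 233 and 103 against 63.5 and 45.6 in shPTPRN3.

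For that reason the fit was repeated, a choice made after seeing the data, without the 267 genes listed at 0 in any library, which also leaves out any gene that was truly silenced. Of 11127 genes, 219 were then called, 42 higher and 177 lower, 10 of them among the 48 above. This count depended on scaling and on single libraries. It was 0 by limma on FPKM as deposited (1547 genes at an unadjusted p under 0.05), 52 on TPM and 126 with quantile normalization, and it was 397 without shNC replicate 1, 607 without shNC replicate 2, 417 without shPTPRN3 replicate 1 and 98 without shPTPRN3 replicate 2. All 219 genes had the same sign in each of these fits. Without a library this was all but fixed in advance, since the groups of the called genes did not overlap. The shared sign is therefore no further support for them. PTPRN was among the lower genes (adjusted p = 0.0270), with 0.0606 on FPKM as deposited and values from 6.63e-05 to 0.0497 in the others. The G2/M list had 33 of 40 members called lower over all genes, the G1/S list 19 of 39 and the DNA repair list 9 of 29, against 20, 7 and 2 without shPTPRN3 replicate 2, 29, 12 and 5 with quantile normalization, 11, 7 and 0 on TPM and 0, 0 and 0 on FPKM as deposited. In all, 61 of the 177 lower genes belonged to these 3 lists. By the rule used above, the largest lower values were those of CDK1, MKI67, PLK1, TK1, CDC20, TROAP, AURKB, RRM2, HJURP, CDCA8, PRC1 and BIRC5, with log2 fold changes from -3.59 to -2.90. The largest higher values were those of MMP3 (2.73), a secreted metalloprotease, CDKN1A (2.72), the interleukin receptor gene IL6R (2.64), the carboxypeptidase gene CPA4 (2.54), SPARC (2.42), BTG2 (2.21), COL1A2 (2.16), FBN1 (2.16), the fibronectin receptor gene ITGA5 (2.14), MMP10 (2.08), the collagen-modifying enzyme gene P3H2 (2.07) and NTNG1 (2.01). MMP3 differed between the knockdown libraries, with 162 and 469 scaled FPKM against 52.6 and 31.3 in shNC. PRC1, TROAP, PLK1, MMP3, CDKN1A, IL6R, SPARC, ITGA5 and P3H2 lie in loci that overlap another gene of the tables, and their values are less certain for it.

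Of the 44 lists fixed before the data were examined, 41 had enough tested members and 11 passed camera, 6 higher and 5 lower. With an estimated correlation 0 passed, and 0 had an unadjusted p under 0.05. A simulated G2/M list of independent genes, truly shifted by -1, also missed with that setting once adjusted beside 40 unshifted lists (camera, adjusted p = 0.280). A miss with an estimated correlation therefore does not show that a list is unchanged. The directional test of fry also passed 0, with 7 at an unadjusted p under 0.05, while its mixed test, which asks whether members change in either direction and does not compare them with other genes, passed 14. By that mixed test G2/M itself missed (adjusted p = 0.0620). So did the MYC targets (0.0512), cholesterol synthesis (0.0656), the unfolded protein response (0.404) and ribosomal proteins (0.644). Lists that missed camera were among those it passed, such as WNT signalling (0.0283). A rank test with the preset correlation passed 14 lists, the 11 above together with metallothioneins (adjusted p = 0.00692), the PI3K and AKT core genes (0.0298) and fatty acid synthesis (0.0166). Lists that did not pass camera included nuclear-encoded oxidative phosphorylation genes (median -0.17 over 45, camera adjusted p = 0.478), hypoxia and glycolysis (0.03 over 37, 0.521), interferon response (0.01 over 32, 0.571), the RNA interference machinery (0.22 over 12, 0.478), apoptosis regulators (0.07 over 23, 0.571), metallothioneins (-1.26 over 8, 0.106) and the PI3K and AKT core genes (0.34 over 24, 0.0586). The direction of the oxidative phosphorylation, hypoxia, interferon and RNA interference lists, and of the leukocyte markers below, turned under at least 1 alternative. The receptor tyrosine phosphatase list, the family of PTPRN, had a median of 0.47 over 10 members (camera, adjusted p = 0.0586). Few markers of other cell types reached the mean of 1 FPKM needed for testing. The 6 neuronal markers had a median of -0.07 (camera, adjusted p = 0.835) and 6 leukocyte markers of 0.10 (adjusted p = 0.912), while 1 of 18 epithelial markers and 0 of 12 endothelial markers reached it. With no filter, 14 epithelial and 11 endothelial markers were tested and neither list passed camera (adjusted p = 0.994 and 0.836). The 13 mRNAs of the mitochondrial genome were not analysed here. The mitochondrial share of all FPKM, which came from rRNA genes, was 0.909% in shNC replicate 1, 2.33% in shNC replicate 2, 1.65% in shPTPRN3 replicate 1 and 2.92% in shPTPRN3 replicate 2, so the groups overlapped. Of genes often used as references, GAPDH had 4565 and 2772 scaled FPKM in shNC and 3475 and 3071 in shPTPRN3 (limma, adjusted p = 0.969). ACTB had 2488 and 1860 in shNC and 1488 and 560 in shPTPRN3 (limma, adjusted p = 0.482), a difference that did not exceed the spread between replicates by this test.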

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

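Leaving out genes listed at 0, leaving out alternate sequences and removing length and GC trends were chosen after seeing the data, as were the repeats of the fit without genes listed at 0; the tests of the difference between replicate numbers were specified before their results were seen. No gene named by the fixed rule and no list reversed its direction where it was past its threshold by either fit compared. Other called genes were not checked this way. Lists that passed in neither fit could turn, such as the NRF2 antioxidant list on TPM and with quantile normalization, the senescence list with quantile normalization and the leukocyte markers with no filter on low values. Against 48 genes called (9 higher, 39 lower, all beyond 2-fold), the count was 31 on FPKM as deposited (23 lower), 30 on TPM (20 lower), 23 with a pseudocount of 0.1 (16 lower) and 26 with eBayes without a trend (19 lower), each beyond 2-fold. It was 8 at a mean of at least 5 FPKM (3 higher, 5 lower) and 0 with no filter on low values, where limma gave 2163 of 19733 genes an unadjusted p under 0.05. It was 160 with robust eBayes (33 higher, 127 lower), 219 without genes listed at 0 (42 higher, 177 lower) and 285 with length and GC trends removed (68 higher, 217 lower), again each beyond 2-fold. At an adjusted p under 0.1 it was 231 (52 higher, 179 lower) and under 0.01 it was 14 (5 higher, 9 lower). It stayed within 1.5 times of 48 with quantile normalization (36), a pseudocount of 0.5 (38), genes of any status (42), the highest entry per symbol (51) and alternate sequences left out (51). The cause of these shifts was not tested.

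The log2 fold change of PTPRN passed the threshold with robust eBayes (-2.22, adjusted p = 0.0363), without genes listed at 0 (-2.22, adjusted p = 0.0270) and with length and GC trends removed (-2.24, adjusted p = 0.0216). Leaving out each library in turn gave -2.45 to -1.98 for PTPRN, with adjusted p under the threshold only without shPTPRN3 replicate 1 (-2.40, adjusted p = 0.0397), 58 to 199 genes called and beyond 2-fold, 10 to 36 higher, 40 to 163 lower, and 8 to 20 lists, 3 to 12 higher and 4 to 8 lower. Such fits leave a group with 1 library, which is assumed to vary like the other group. With an estimated correlation and with fry, 0 lists passed, 0 higher and 0 lower (0 and 7 at an unadjusted p under 0.05, against 16 by camera). Of the single named genes, 58 comparisons with an alternative newly passed and 72 no longer did, and 644 stayed on their side; for lists the numbers were 33, 32 and 875.

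The labels number the libraries 1 and 2 in both groups and say nothing of what a number shares, so a replicate block is given only here. Across genes, the deviations of same-numbered libraries from their group means correlated with r = 0.519. With the replicate block 2168 genes were called (956 higher, 1212 lower, 1197 beyond 2-fold) and PTPRN had -2.22 (adjusted p = 9.07e-07). With the replicate block and length and GC trends removed, 1992 were called (897 higher, 1095 lower, 1070 beyond 2-fold) and PTPRN had -2.24 (adjusted p = 3.93e-04). Both blocked fits leave fewer residual degrees of freedom than the 2 of the unblocked fit. Their p-values therefore lean more on the prior spread taken from all genes. The larger counts and smaller p-values are no firmer support for that reason. The difference between numbers correlated with transcript length across genes (rho = 0.689 in shNC, 0.414 in shPTPRN3), but removing length and GC trends left r = 0.376, which argues against length as its whole cause. Depth as a cause is argued against by the SD of that difference above 50 FPKM, 0.769 in shNC and 0.673 in shPTPRN3. In the group where the ratio was lower, this SD was 1.13 times that at 1 to 5 FPKM. The pseudocount of 1 shrinks differences at 1 to 5 FPKM and so raises that ratio. A shared day or culture stays open and was not tested. Splitting the libraries by number called 6 genes and the crossed split 0, against 48 for the real split; 3 splits are too few for a share under 0.05.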

Other observations

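The seed-site share, the shift of seed-site genes, the random placement of zeros and the overlapping partner were specified before their results were seen. The other tests below were chosen after. A list of senescence-associated and secreted genes did not pass as a set (median log2 fold change 0.07 over 21 members, camera adjusted p = 0.940), yet 4 members rose and 7 fell when adjusted over the list alone, and none passed over all genes tested. Those that rose were CDKN1A (2.72), MMP3 (2.73), MMP10 (2.08) and the lysosomal galactosidase gene GLB1 (means of 40.4 and 94.4 scaled FPKM). The numbers depended on single libraries: without shNC replicate 2, 0 rose and 2 fell, without shNC replicate 1, 3 fell, without shPTPRN3 replicate 2, 1 fell, and with no filter on low values 2 fell. Those that fell were PLAU (-2.19), HMGB2 (-2.16), the chemokine gene CCL2 (-2.04), the nuclear lamina gene LMNB1 (-1.94), TNFRSF1B (-1.30), HMGB1 (-1.21) and the chemokine gene CXCL8 (-0.99). IL6 (-0.18) and IL1B (0.05) were near 0. These genes were named after their values were seen. Camera and the median weigh direction, so members of this list that moved opposite ways cancel. The miss by camera therefore does not show that the list is unchanged. The mixed test of fry, which asks for change in either direction, passed the list (adjusted p = 0.0450).

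Among receptor tyrosine phosphatases, PTPRU had a mean of 0.272 scaled FPKM in shNC and 3.04 in shPTPRN3 and was called higher in the fit without genes listed at 0 (limma, log2 fold change 1.67, adjusted p = 0.0270). In that fit the list passed camera (median 0.47 over 10 members, adjusted p = 0.0440), as did metallothioneins (median -1.33 over 7, adjusted p = 0.0472) and the PI3K and AKT core genes (0.34 over 24, adjusted p = 0.0472). Their adjusted p were 0.732, 0.842 and 0.908 with an estimated correlation.

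The genes called because they were listed at 0 in both libraries of a group form the first pattern. All 37 of them, or 100%, overlap another gene, against 28.5% of other tested genes (Fisher's exact test, two-sided, p = 8.36e-21), as failed FPKM estimates at shared loci would give. Of 89 genes at 0 in exactly 2 libraries, 51, or 57.3%, had both in the same group. Chance gives 33.3% (exact binomial test, two-sided, p = 4.38e-06), which argues against failures spread evenly over pairs of libraries. The shPTPRN3 pair held 37 of them and the shNC pair 14, against 19, 10, 6 and 3 for pairs across groups. The 19 were those of the libraries numbered 2, so zeros did not follow the group in shNC. The chance share also assumes libraries equally prone to zeros. The overlapping partner was higher in the group listed at 0 in 29 of 35 pairs, by a median of 0.54 on the log2 scale (exact sign test, two-sided, p = 1.17e-04), as for CTSA beside PLTP and ALYREF beside ANAPC11. A candidate explanation is that reads of these genes went to the partner where the partner's level was higher, and a true loss of single genes among the 37 stays open.

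The second pattern is the fall of G2/M and G1/S genes. Library scaling is argued against by a median of -1.47 at its nearest to 0 over both lists and the scalings tried. For G2/M, transcript length and GC content are argued against by a median of -2.43 with both trends removed. That test was set for the G2/M list only. The G1/S median ran from -2.00 to -1.31 over 23 alternatives, removal of both trends among them. A difference between replicate numbers is balanced over the groups, so the within-number median nearest to 0, -1.32, does not test it. Direct repression through the seed site CAGGATG in 3' UTRs is argued against by the 73 list genes without a site, whose median was -1.96. This site assumes a guide that is the exact reverse complement of the target sequence. Only the longest transcript of each gene was searched, and other cuts of the hairpin and its other strand were not tested. A site was present in 11.0% of list genes, against a mean of 9.25% of genes in random sets matched on 3' UTR length (permutation p = 0.346). That share met neither outcome set for its test. Over 10325 genes the shift of genes with a site was -0.07, with 8% of 200 control heptamers as low. Reduced proliferation of cells carrying the hairpin stays open as a hypothesis found on these data, which no test here decides, since the tables hold no measure of cell growth. An effect of the lost PTPRN, an off-target effect on an upstream regulator and an effect of carrying any hairpin were not separated by this design. It has 1 hairpin, and its control was the empty vector, per the labels' protocol. Culture density at harvest was not tested.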
